A study of Mus musculus with 6 samples.

How the data were processed

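The samples were 6 arrays of RNA from corticothalamic projection neurons of C57BL/6 mice, the cortical neurons whose axons reach the thalamus. Per the labels' protocols, the neurons took up green fluorescent microspheres injected into the thalamus and were later purified from dissociated cortex by fluorescence-activated cell sorting. Injections were made at E17.5, P1 and P4, and cortex was taken at E18.5, P3 and P6. The sample names call the first stage E18, and that name is used here. Per the labels, RNA was extracted with a StrataPrep micro kit and amplified and biotinylated with an Enzo BioArray kit. Each stage had 2 arrays.

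The deposited values are log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects background, normalizes probes across the arrays it is given and summarises each probe set. Whether the 6 arrays were run through it together was not given, and the SD of their log2 values ran from 1.85 on P3 replicate 2 to 2.16 on E18 replicate 2. Its version and the annotation used with it were not given in the sources used here. The deposited columns were kept as they stood. Array signals are relative, so their number limits the precision and no read depth exists. Values near the low end of an array understate a fold change, because background then makes up most of the signal. No detection call per probe set was used here.

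Probe sets were named from the platform annotation table supplied with the series. Of 45101 probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were controls. Probe sets with several symbols or none were left out. The Entrez IDs of 34741 probe sets were found in the RefSeq gene table, and 0 symbols needed updating. This gave 18193 genes, each represented by its probe set with the highest mean over the 6 arrays. The 25% of genes with the lowest means were left out, which kept 13645 genes with means of at least 5.97. Other probe sets of a gene could disagree with the chosen probe set. Among the called genes with more than 1 probe set, all probe sets moved the same way for 2065 of 3373 genes between E18 and P3 and for 1948 of 2704 between E18 and P6.

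Stage means were fitted with limma 3.58.1 in R 4.3.3 on all 6 arrays together, with 3 residual degrees of freedom. Empirical Bayes moderation used an intensity trend. The contrasts were P3 minus E18, P6 minus P3, P6 minus E18, a moderated F-test over the 3 stages, and the change in the second interval minus the change in the first. All tests were 2-sided. Adjusted p-values follow Benjamini and Hochberg within each contrast, and a gene was called at an adjusted p below 0.05. Errors of log2 changes are standard errors (SE) from this fit, and every stage mean rests on n = 2 arrays.

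Before the data were examined, 28 gene lists were fixed, covering neuron classes, functions of neurons and markers of other cell types. Of their 758 members, 674 matched a probe set with 1 symbol and 617 were tested. A list needed at least 5 tested members, which left out the lists of Cajal-Retzius cells and red blood cells, with 3 tested genes each. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01. It asks whether members shifted in 1 direction relative to other genes. A list whose members move both ways can therefore go uncalled. Alternatives were camera with the correlation estimated per list, and fry, whose directional p asks whether members moved 1 way on balance. With the correlation estimated, camera refers its statistic to the 3 residual degrees of freedom. A lost call then need not mean correlated genes. For P3 minus E18 the proliferation and postsynaptic lists had estimated correlations of -0.023 and -0.005, below the preset. Their camera adjusted p was still 0.081.

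The rule for named genes was also fixed before the data were examined. It took the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the stages, and 6 in each direction for the unequal change. It also took up to 4 members of each list with the smallest p in a comparison. In every comparison it took Tbr1, Tle4, Foxp2, Zfpm2, Sox5, Fezf2, Bcl11b, Ntsr1, Syt6, Crym and Ccn2. Symbols that only number a clone or prediction were passed over.

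The gene test was tried on simulated data with 200 of 13645 genes changed, in 10 runs, and the list test with 1 list shifted, also in 10 runs. With spread pooled over the stages, the test recovered 56.1% of 4-fold changes and 6.5% of 2-fold changes in P3 minus E18, and 2.34% of calls were false. For P6 minus P3 the shares were 59.2%, 7.5% and 2.77%, and for P6 minus E18 they were 55.2%, 8.3% and 3.5%. When each stage kept its own spread, the false share was 28.28% for P3 minus E18, 49.49% for P6 minus P3 and 13.61% for P6 minus E18. Each gene's own spread came from 2 arrays per stage, so it mixes estimation noise with unequal spread between stages. These shares depend on the number of changed genes. In the data limma called 5629 genes for P3 minus E18 and 4320 for P6 minus E18, so the shares do not carry over to those comparisons. A presynaptic list shifted by 1 log2 unit in P6 minus P3 was called in 10 of 10 runs, with 0 other lists called. The simulated genes varied independently, while the estimated correlation of this list in the data was 0.311. These runs therefore do not test camera's preset on correlated genes.

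Alternatives set in advance were no filter, leaving out the lowest 50% of genes, no intensity trend, quantile normalization of the deposited values, the mean of all probe sets, and each probe set on its own. Others were the replicate number as a block, leaving out each array in turn, fitting only the stages compared, a 2-fold minimum, and limma's array weights. Chosen after seeing the data were averaging the E18 arrays into 1 sample, the level of the hybridization controls or of the 18S probe sets as a covariate, and fits without the arrays whose controls stood apart. The hybridization control level was low on the E18 arrays and P6 replicate 2 and high on the others, so only the P6 arrays inform it. With it as a covariate, P6 minus E18 rests on P6 replicate 2 alone and P6 minus P3 on P6 replicate 1 alone. P3 minus E18 is then shifted by the difference between the P6 arrays. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 handled the tables and plots.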

Results

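The series followed corticothalamic projection neurons of mouse cortex across 3 stages around birth, with 2 arrays each at E18, P3 and P6. The labels name no control group, so the comparisons are between stages. They ask which genes differ as these neurons pass from the end of axon growth to early circuit formation. Nothing in the labels says whether the 2 arrays of a stage came from separate animals or sorts, so p-values measure only the spread between these arrays. Injection preceded collection by 1 day at E18 and by 2 days at P3 and P6, so labelling time cannot be told apart from stage in comparisons with E18.

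The arrays of a stage were not equally alike. The E18 arrays correlated at 0.998 across probe sets, with an SD of their log2 differences of 0.126, and 0 probe sets differed by more than 2-fold. The P3 arrays correlated at 0.961, with 3661 probe sets over 2-fold apart, and the P6 arrays at 0.977, with 1689. The first principal component held 72.3% of the variance and separated E18 from the later stages. The second held 16.2% and set P3 replicate 2 apart. Hybridization controls, which are transcripts added before hybridization, averaged at most 9.86 log2 units at E18, 11.91 and 11.73 at P3, and 13.13 and 10.06 at P6. The 18S ribosomal RNA probe sets stood at 14.22 on P3 replicate 2 and 13.92 on P6 replicate 1, against 11.32 to 11.83 on the other arrays. The excess of 3' over 5' signal of Actb was 0.56 and 0.58 log2 units at E18, 1.19 and 1.76 at P3, and 1.06 and 0.82 at P6. For Gapdh it was 1.48 and 1.44 at E18, 2.55 and 1.68 at P3, and 2.08 and 1.79 at P6.

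**Figure D1:**
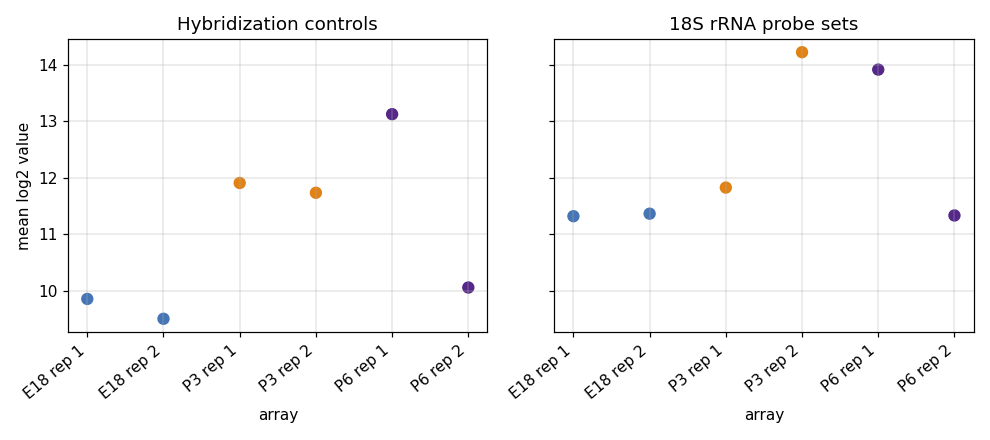
Mean log2 value of the hybridization control probe sets (left) and the 18S ribosomal RNA probe sets (right) on each of the 6 arrays, 1 point per array, coloured by stage. P3 replicate 2 and P6 replicate 1 stand at 14.22 and 13.92 for 18S, and the E18 arrays and P6 replicate 2 hold the lowest hybridization controls.

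Between E18 and P3, genes of dividing cells and neural progenitors had the lowest medians of the 26 lists tested, with 22 of 23 and 12 of 14 genes lower. Of the presynaptic, ion channel and corticothalamic lists, 24 of 37, 27 of 43 and 13 of 17 genes rose. Camera called these lists at its preset correlation, and 0 lists with an estimated correlation, where 4 had an unadjusted p under 0.05. Celsr1, an atypical cadherin of planar polarity, was 115-fold lower at P3 (SE 0.20 log2 units, limma adjusted p = 6.42e-06). The progenitor transcription factor Sox2 was 108-fold lower (SE 0.48, adjusted p = 7.4e-05), and the proneural factor Neurog2 was 85.1-fold lower (SE 0.32, adjusted p = 1.71e-05). Vsnl1, a neuronal calcium sensor, was 19.5-fold higher at P3 (SE 0.23, adjusted p = 2.33e-05), and the metabotropic glutamate receptor gene Grm3 was 18.7-fold higher (SE 0.26, adjusted p = 3.89e-05).

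The other large falls were mostly in cell-cycle genes. The mitotic kinase gene Pbk was 105-fold lower, the DNA topoisomerase gene Top2a 95.8-fold, the cohesion factor gene Cdca5 84.0-fold and Cdk1 77.3-fold. Sox3 was 78.9-fold lower, the intermediate filament gene Vim 69.9-fold and the proliferation marker gene Mki67 69.6-fold. Limma's adjusted p for these 7 genes was at most 1.11e-05. Celsr1, Sox2 and Neurog2 stood at 4.11, 5.35 and 5.44 log2 units at P3, near or below the lower quartiles of the P3 arrays, 5.27 and 5.40. The other large rises were in Stxbp5l, which encodes a syntaxin-binding protein (18.8-fold), the calcium-binding protein gene Necab1 (18.7-fold), the G-protein subunit gene Gng4 (18.52-fold) and the guanine deaminase gene Gda (18.2-fold). Cdkl2 rose 17.9-fold, Pdzd2 17.54-fold, Syndig1l 17.4-fold and Cyria 16.7-fold, with limma's adjusted p at most 0.000169 for these 8 genes.

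Genes that mark corticothalamic neurons rose as a group, in a comparison where progenitor and proliferation genes fell by medians of -4.44 and -5.00 and the excess of 3' over 5' signal of Actb went from 0.56 and 0.58 at E18 to 1.19 and 1.76 at P3. A change in the share of RNA from these neurons or in RNA quality was not separated from a change within them. Of 17 tested members of the corticothalamic and layer 6 list, 13 rose and 0 fell over all genes tested, and the same counts held adjusted over the list alone. The median change was 1.59 log2 units (camera adjusted p = 2.92e-06, but adjusted p = 0.37 with an estimated correlation). The layer 6 transcription factor genes Tbr1, Tle4, Foxp2, Zfpm2 and Sox5 were 2.57-fold, 4.33-fold, 5.44-fold, 2.46-fold and 2.52-fold higher at P3, with SEs of 0.35, 0.24, 0.28, 0.31 and 0.30 log2 units and adjusted p of 0.0198, 0.00069, 0.000756, 0.016 and 0.0131. Without P3 replicate 1 the change of Tbr1 was 0.89 against 1.36. The neurotensin receptor gene Ntsr1, a layer 6 marker, rose 5.47-fold, Crym 5.94-fold, Syt6 3.02-fold, the heparan sulfate enzyme gene Hs3st4 12.4-fold and the kainate receptor gene Grik3 7.48-fold. Fezf2, which directs deep-layer neuron identity, changed by -0.45 ± 0.35 (SE; adjusted p = 0.317), and Bcl11b, a marker of subcerebral neurons, by 0.09 ± 0.40 (adjusted p = 0.864). Neither passed the test. Fezf2 lay between -0.70 and -0.20 without P3 replicate 1 or 2, and Bcl11b stood at -0.56 without P3 replicate 1, where limma called it lower, and at 0.74 without P3 replicate 2, where limma called it higher. With the mean of all its probe sets it stood at 1.37 and was called (adjusted p = 0.0147). With the E18 arrays averaged, Tbr1, Zfpm2 and Sox5 lost their calls at adjusted p of 0.0988, 0.1 and 0.0739 with the same fold. Leaving out E18 replicate 1 or 2 ended the same 3 calls, with adjusted p from 0.0693 to 0.116. Syt6 lost its call without P6 replicate 1 or 2, at adjusted p of 0.0524 and 0.0526, and also with only the stages compared (0.0527) and with the 18S level as a covariate (1.27, 0.0599). Its change was 0.91 without P3 replicate 2, against 1.59. With the hybridization control level as a covariate, Tbr1, Tle4, Foxp2, Zfpm2, Sox5, Ntsr1, Syt6, Crym and Grik3 all lost their calls, with adjusted p from 0.0545 to 0.362. Their changes then lay between 1.01 (Tbr1) and 2.79 (Crym) with wider errors, such as an SE of 0.64 for Tbr1. The list itself stayed called, with a median of 1.67 (camera adjusted p = 2.03e-05). In that fit, where only the P6 arrays inform the control level, Fezf2 turned to 0.44 and was not called (limma adjusted p = 0.556).

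Synaptic and excitability genes moved the same way, beside the falls in progenitor, proliferation and glial markers given below, so their rise is likewise not shown to be within the neurons. Of 37 presynaptic genes, 24 rose and 2 fell (25 and 3 adjusted over the list alone), including the SNARE genes Snap25 (10.5-fold) and Stx1a (6.01-fold). The list median was 1.27 (camera adjusted p = 3.14e-09, and adjusted p = 0.37 with an estimated correlation). Of 43 voltage-gated channel genes, 27 rose and 2 fell (29 and 3 adjusted over the list alone), with the sodium channel gene Scn2a up 13.0-fold. Their median was 1.26 (camera adjusted p = 6.58e-10, and adjusted p = 0.11 with an estimated correlation). Of 41 postsynaptic genes, 19 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 3.4e-08, and adjusted p = 0.081 with an estimated correlation). Neurite growth genes had 16 rises and 5 falls among 35 (17 and 5 adjusted over the list alone), and the growth cone gene Gap43 rose 4.82-fold and the neuronal tubulin gene Tubb3 3.61-fold. Their median was 0.55 (camera adjusted p = 5.76e-05, and adjusted p = 0.54 with an estimated correlation). Subcerebral layer 5 genes had 7 rises and 2 falls among 12, the same adjusted over the list alone, with S100a10 up 7.85-fold and Pcp4 up 4.78-fold. Their median was 0.96 (camera adjusted p = 0.00719, and adjusted p = 0.37 with an estimated correlation). Neuronal transcription factors went both ways, with 13 rises and 6 falls among 28 (16 and 6 adjusted over the list alone). Klf9 rose 7.08-fold and Zbtb20 fell 15.6-fold, and the median was 0.85 (camera adjusted p = 0.0104, and adjusted p = 0.37 with an estimated correlation). That call was lost with no filter on dim genes (median 0.81, camera adjusted p = 0.0623) and with the hybridization control level as a covariate (0.775, camera adjusted p = 0.0534). Among GABA receptor and chloride transport genes, 6 of 12 rose and 2 fell, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.0694). Fry did call it (adjusted p = 0.005). The chloride exporter gene Slc12a5 rose 5.50-fold and the receptor subunit gene Gabrb2 12.4-fold. With the control level in the fit, Slc12a5 (2.34, adjusted p = 0.0729) and Tubb3 (1.44, adjusted p = 0.0532) were not called.

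Markers of several other cell types stood high on the E18 arrays. Of 23 proliferation genes, 22 fell and 0 rose, also adjusted over the list alone, with a median of -5.00 (camera adjusted p = 1.01e-13, and adjusted p = 0.081 with an estimated correlation). Of 14 radial glia and progenitor markers, 12 fell and 0 rose over all genes tested, and 12 fell and 1 rose adjusted over the list alone. The probe set chosen for Pax6 was dim, at 5.86 at E18 and 6.52 at P3, while another of its probe sets went from 9.77 to 4.60. Notch1 fell 51.8-fold and Eomes, a factor of intermediate progenitors, 46.2-fold. The list median was -4.44 (camera adjusted p = 1.34e-07, and adjusted p = 0.11 with an estimated correlation). Among 16 astrocyte markers, 9 fell and 1 rose (9 and 2 adjusted over the list alone), with Aldh1l1 down 39.4-fold and Id3 24.4-fold, and a median of -1.34 (camera adjusted p = 0.00215, and adjusted p = 0.54 with an estimated correlation). Without P3 replicate 1 the astrocyte list had a median of -1.24 and was not called (camera adjusted p = 0.067). Of 13 microglia and macrophage markers, 10 fell (12 adjusted over the list alone), with the complement gene C1qa down 10.8-fold and the protease gene Ctss 9.61-fold, and a median of -1.95 (camera adjusted p = 0.00172, and adjusted p = 0.63 with an estimated correlation). Without P3 replicate 1 the microglia list was not called (median -1.56, camera adjusted p = 0.136). With the hybridization control level as a covariate its median was -0.49 and it was not called (camera adjusted p = 0.206), and C1qa (-1.27, adjusted p = 0.251) and Ctss (-1.78, adjusted p = 0.287) lost their calls. Fry did not call the microglia list either (adjusted p = 0.0503). The ribosomal protein genes had 28 falls and 1 rise among 42 (30 and 1 adjusted over the list alone), with Rplp0 down 2.28-fold, a call lost with that covariate (-0.89, adjusted p = 0.18). Their median was -0.75 (camera adjusted p = 8.19e-05, and adjusted p = 0.63 with an estimated correlation), against -0.13 for all genes tested.

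In all, limma called 5629 of 13645 genes between E18 and P3, of which 2116 rose and 3513 fell, so that 37.6% of calls were higher at P3. With quantile normalization 52.8% of calls were higher, and the median of all genes moved from -0.13 to 0.12. The count was 2452 with the E18 arrays averaged, 2569 and 2397 without E18 replicate 1 or 2, and 1279 with the hybridization control level as a covariate, a fit in which 16 of the 64 named genes called here were no longer called. The stages shared 1 estimate of spread, which the closely matched E18 arrays lowered, so some calls between P3 and E18 rest on a spread smaller than that of P3.

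**Figure D2:**
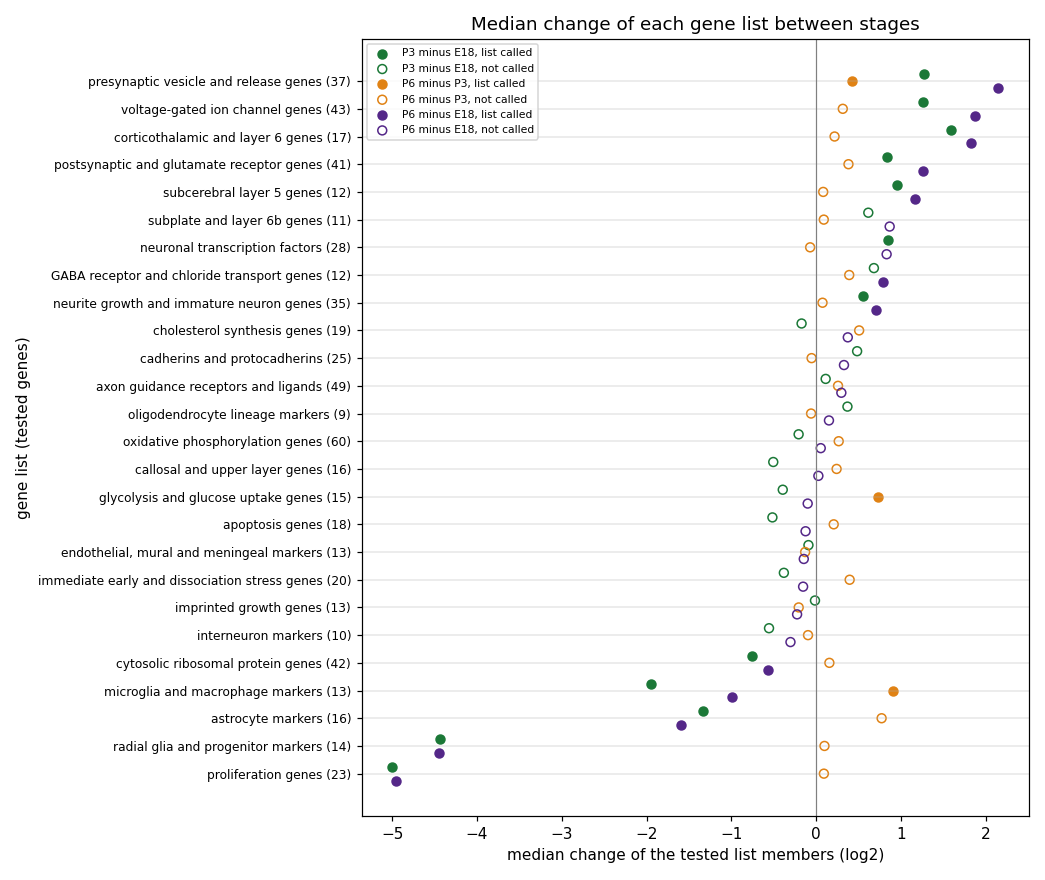
Median log2 change of the tested members of each of 26 gene lists (rows, with the number of tested genes) for the 3 comparisons, with filled points where camera called the list at its preset correlation. Proliferation genes lie at -5.00 for P3 minus E18 and -4.95 for P6 minus E18, and presynaptic genes at 1.27 and 2.15.

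Between P3 and P6, no single gene passed the test, and the values below are of genes with the smallest p in their lists. The potassium channel subunit gene Kcnf1 was higher at P6 by 1.94 ± 0.21 log2 units (SE), and the transcription factor gene Rorb, a layer 4 marker, differed by -1.88 ± 0.23, each with a limma adjusted p = 0.0981, the smallest of the comparison. Among astrocyte markers, Apoe differed by 2.55 ± 0.51 and Aldoc by 2.12 ± 0.43 (adjusted p = 0.113 for both). Limma called 0 of 13645 genes, with 2696 genes at an unadjusted p under 0.05. That number would be 682 by chance with equal spread. In simulated data with each stage's own spread 14.46% of unchanged genes had such a p. That spread came from 2 arrays per gene and stage, so the share mixes estimation noise with unequal spread. How much of the excess comes from unequal spread was not measured. The same fit called 0 genes with array weights, and the list test fry called 0 lists with 7 at an unadjusted p under 0.05.

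Camera called 3 lists, all higher at P6. It did not call the astrocyte list (adjusted p = 0.0693), whose median was 0.77, with 7 of 16 genes higher and 0 lower adjusted over the list alone. A change in the share of RNA from the neurons or in RNA quality was not separated from a change within them in this interval either. The glycolysis and glucose uptake list had a median of 0.73 over 15 genes (camera adjusted p = 0.00212, but adjusted p = 0.59 with an estimated correlation). Its leading members were the neuronal enolase gene Eno2 at 1.46 ± 0.30, the phosphofructokinase gene Pfkl at 1.19 ± 0.26 and the glucose transporter gene Slc2a3 at 1.14 ± 0.26. Adjusted over the list alone, 9 of the 15 passed the test. The presynaptic list had a median of 0.43 over 37 genes (camera adjusted p = 0.00212, but adjusted p = 0.7 with an estimated correlation). Syt13, a synaptotagmin gene, differed by 1.91 ± 0.37 and the vesicle SNARE gene Vamp2 by 1.35 ± 0.29, and 12 genes were higher and 1 lower adjusted over the list alone. The microglia and macrophage list had a median of 0.91 over 13 genes (camera adjusted p = 0.00816, but adjusted p = 0.74 with an estimated correlation), with Fcrls at 1.28 ± 0.32 and Cd68 at 1.04 ± 0.29, or 0.57 without P6 replicate 2. Adjusted over that list alone, 4 were higher. The microglia call was lost without P6 replicate 2 (median 0.46, camera adjusted p = 0.447) and without P3 replicate 1 (median 0.65, camera adjusted p = 0.785), and the median was 1.61 without P6 replicate 1, where camera called 9 lists. It was also lost with the lowest 50% of genes left out (camera adjusted p = 0.107) and with the 18S level as a covariate (camera adjusted p = 0.0865). With the hybridization control level as a covariate camera called 0 lists, with 4 at an unadjusted p under 0.05. The glycolysis and presynaptic medians were then 0.643 and 0.401, each at a camera adjusted p = 0.0519. Among the arrays with high hybridization controls alone it also called 0, with 6 at an unadjusted p under 0.05.

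Corticothalamic genes showed no shift past the test in this interval, with a list median of 0.22 (camera adjusted p = 0.829) and 0 of 17 members called, also adjusted over the list alone. Crym differed by 1.38 ± 0.36 log2 units (adjusted p = 0.139), Ccn2 by 1.39 ± 0.36 (adjusted p = 0.134), Bcl11b by 1.13 ± 0.40 (adjusted p = 0.192) and Ntsr1 by 0.76 ± 0.36 (adjusted p = 0.287). Without P3 replicate 2 these 4 values were 0.84, 0.85, 0.48 and 0.33, and without P3 replicate 1 they were 1.91, 1.94, 1.78 and 1.19, where limma called all 4. Fezf2 stood at 0.64 ± 0.35, Tbr1 at 0.55 ± 0.35, Zfpm2 at 0.52 ± 0.31, Tle4 at 0.37 ± 0.24, Sox5 at 0.22 ± 0.30, Syt6 at -0.06 ± 0.40 and Foxp2 at -0.38 ± 0.28, with adjusted p from 0.348 to 0.948. Under quantile normalization, the mean of all probe sets or leaving out P3 replicate 2, Sox5 took the opposite sign, and Syt6 did so in the last of these, at 0.62. With the mean of all its probe sets, Bcl11b stood at -0.018. Without P3 replicate 2, Tbr1, Zfpm2 and Tle4 stood at 0.075, 0.12 and 0.13. Without P6 replicate 2, Fezf2 stood at 0.19 and Foxp2 at -0.06. Other members named by the rule were Slit1, an axon repellent gene, at 1.79 ± 0.32, the telencephalic adhesion gene Icam5 at 1.74 ± 0.32, the GABA receptor gene Gabra4 at 1.86 ± 0.37, Slc12a5 at 0.97 ± 0.30, the lipase gene Lpl at 1.44 ± 0.25 and the immature neuron gene Dcx at -1.22 ± 0.32. Dcx was -0.71 without P6 replicate 1, and Slc12a5 was 0.585 without P3 replicate 2 and 1.355 without P3 replicate 1. The count of called genes depended on the P3 arrays. Without P3 replicate 1 limma called 3922 genes, 3330 of them higher at P6, and 19 of the 28 genes named for this interval. That fit sets P3 replicate 2 alone, the array apart on the second component and in 18S, against P6, with its spread from E18 and P6 only, so its calls do not establish a change between the stages. Without P3 replicate 2 limma called 0 genes. The arrays with high hybridization controls alone gave 57 calls, with a single P6 array among them, and the 18S level as a covariate gave 516. In that last fit 8 of the 28 named genes were called, with Kcnf1, Rorb, Lpl, Eno2, Pfkl and Syt13 at adjusted p = 0.0472 and Slc2a3 and Gabra4 at 0.048.

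Across the whole span from E18 to P6, 31 of 37 presynaptic, 33 of 43 ion channel and 14 of 17 corticothalamic genes rose, and 12 of 14 progenitor markers fell. Camera called these lists at its preset correlation, and 0 lists with an estimated correlation, where 4 had an unadjusted p under 0.05. Rprml rose 33.7-fold (SE 0.37 log2 units, limma adjusted p = 8.79e-05) and the matricellular gene Ccn3 31.1-fold (SE 0.25, adjusted p = 1.96e-05). Neurog2 fell 126-fold (SE 0.32, adjusted p = 1.49e-05) and Celsr1 106-fold (SE 0.20, adjusted p = 7.7e-06). Neurog2 stood at 4.88 at P6, below the lower quartiles of the P6 arrays, 5.27 and 5.20, where background makes a fold imprecise. The corticothalamic marker Crym rose 15.4-fold (SE 0.36, adjusted p = 0.000236), from 7.34 log2 units at E18 to 11.29 at P6.

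The remaining large rises were in Gng4 (28.9-fold), the unconventional myosin gene Myo5b (27.7-fold), the neuronal pentraxin gene Nptx1 (25.3-fold), the surface glycoprotein gene Thy1 (24.2-fold), Syndig1l (23.6-fold), Ramp3 (22.8-fold), the neuropeptide gene Cck (22.5-fold) and Vsnl1 (21.4-fold). Limma's adjusted p for these 8 genes was at most 0.000387. The remaining large falls were in Sox2 (97.5-fold), Top2a (91.5-fold), Cdk1 (74.9-fold), the kinetochore gene Nuf2 (73.4-fold), Nusap1 (73.0-fold), Pbk (70.2-fold), Sox3 (67.6-fold) and Eomes (67.1-fold), with adjusted p at most 8.08e-05.

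Of the 17 corticothalamic and layer 6 genes, 14 rose and 0 fell, also adjusted over the list alone, with a median of 1.82 log2 units (camera adjusted p = 1e-05, but adjusted p = 0.45 with an estimated correlation). Proliferation genes fell by a median of -4.95, and the excess of 3' over 5' signal of Actb was 1.06 and 0.82 at P6 against 0.56 and 0.58 at E18. For this and the other neuronal lists, a change in RNA share or quality was not separated from a change within the neurons. Ntsr1 rose 9.28-fold, Tle4 5.60-fold, Foxp2 4.18-fold, Tbr1 3.75-fold, Zfpm2 3.54-fold, Sox5 2.93-fold and Syt6 2.90-fold, with SEs from 0.24 to 0.40 log2 units and adjusted p at most 0.0235. Hs3st4 rose 11.8-fold and Grik3 7.27-fold. Bcl11b stood at 1.22 ± 0.40 (adjusted p = 0.0522) and Fezf2 at 0.19 ± 0.35 (adjusted p = 0.698). Limma called Bcl11b without P3 replicate 1 or 2, at adjusted p of 0.00168 and 0.00161 and the same 1.22, and with the mean of all its probe sets (1.35, adjusted p = 0.0169). Syt6 lost its call with the E18 arrays averaged (adjusted p = 0.0519), and its adjusted p lay between 0.0516 and 0.129 without either E18 array or either P6 array. Its call also ended with quantile normalization (1.49, adjusted p = 0.0635) and with the 18S level as a covariate (1.21, 0.0765). Without P6 replicate 1, Tbr1 (1.73) and Sox5 (1.495) were not called, at adjusted p of 0.0571 and 0.0639. With the hybridization control level as a covariate, Tbr1, Sox5 and Syt6 lost their calls too. That fit also rests on P6 replicate 2 alone, so this is not separate evidence.

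Presynaptic genes rose in 31 of 37 cases and fell in 2 (34 and 2 adjusted over the list alone), with Snap25 up 11.6-fold and Stx1a up 7.53-fold, and a median of 2.15 (camera adjusted p = 2.87e-12, and adjusted p = 0.4 with an estimated correlation). Of 43 voltage-gated channel genes, 33 rose and 1 fell (34 and 1 adjusted over the list alone), with Scn2a up 13.6-fold and Kcnf1 up 10.7-fold, and a median of 1.88 (camera adjusted p = 6.17e-12, and adjusted p = 0.084 with an estimated correlation). Of 41 postsynaptic genes, 31 rose and 0 fell (33 and 1 adjusted over the list alone), with the NMDA receptor gene Grin3a up 12.8-fold, and a median of 1.26 (camera adjusted p = 2.39e-10, and adjusted p = 0.056 with an estimated correlation). GABA receptor and chloride transport genes had 7 rises and 1 fall among 12 (8 and 2 adjusted over the list alone), with Slc12a5 up 10.8-fold and a median of 0.79 (camera adjusted p = 0.0134, and adjusted p = 0.31 with an estimated correlation). The GABA call was lost, with medians little changed or higher, with the lowest 50% of genes left out (0.76, camera adjusted p = 0.0765), with the mean of all probe sets (0.89, 0.0992), without the arrays of high 18S (0.95, 0.0568) and in the arrays with low hybridization controls (0.95, 0.0581). Neurite growth genes had 18 rises and 2 falls among 35 (20 and 2 adjusted over the list alone), with Gap43 up 4.23-fold and Tubb3 up 4.32-fold, and a median of 0.71 (camera adjusted p = 0.000138, and adjusted p = 0.51 with an estimated correlation). The neurite growth median was 0.45 without P6 replicate 1, with the list still called. Of 12 subcerebral layer 5 genes, 6 rose and 0 fell (7 and 2 adjusted over the list alone), with a median of 1.17 (camera adjusted p = 0.0174, and adjusted p = 0.45 with an estimated correlation). That call was lost without P6 replicate 2 (camera adjusted p = 0.0594) and with the mean of all probe sets (0.0695).

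The falling lists were those of the first interval. Proliferation genes fell in 22 of 23 cases, also adjusted over the list alone, with a median of -4.95 (camera adjusted p = 9.01e-18, and adjusted p = 0.056 with an estimated correlation). Progenitor markers fell in 12 of 14 cases (12 lower and 1 higher adjusted over the list alone), with a median of -4.44 (camera adjusted p = 2.68e-10, and adjusted p = 0.084 with an estimated correlation). The 2 members not called had other probe sets that were lower at P6, for Pax6 9.77 at E18 and 4.40 at P6. Astrocyte markers had 9 falls and 1 rise among 16, also adjusted over the list alone, with Aldh1l1 down 22.4-fold and Id3 11.2-fold, and a median of -1.59 (camera adjusted p = 0.00561, and adjusted p = 0.54 with an estimated correlation). The astrocyte call was lost without the arrays of high 18S (-1.09, camera adjusted p = 0.0739) and in the arrays with low hybridization controls (camera adjusted p = 0.0661). Ribosomal protein genes had 16 falls and 0 rises among 42 (18 and 0 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 1.7e-05, and adjusted p = 0.65 with an estimated correlation). Fry did not call the ribosomal list (adjusted p = 0.0868). Of 13 microglia markers 1 fell (0 adjusted over the list alone), and C1qa stood at -1.85 ± 0.65 (adjusted p = 0.0683). C1qa was -2.93 and called without P6 replicate 2 (adjusted p = 0.0118), and -0.77 without P6 replicate 1. Limma also called it with array weights (adjusted p = 0.00118). The microglia median was -0.99 (camera adjusted p = 0.0462, and adjusted p = 0.68 with an estimated correlation). That call was lost without P6 replicate 1 (median -0.28, camera adjusted p = 0.352) and without P3 replicate 1 or 2 (camera adjusted p = 0.103 and 0.104), and the median was -1.66 without P6 replicate 2. It was also lost with quantile normalization (-0.79, camera adjusted p = 0.101), the mean of all probe sets (-0.72, 0.051), and fry (adjusted p = 0.275). The hybridization control level as a covariate gave the same median of -0.28 as leaving out P6 replicate 1, because it uses the same P6 array.

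In all, limma called 4320 genes between E18 and P6, 2015 higher and 2305 lower at P6, against 2477 higher and 2307 lower with quantile normalization. The count was 2366 with the E18 arrays averaged, and 2391 and 2338 without E18 replicate 1 or 2. Limma called 3007 genes with the hybridization control level as a covariate, and 10229 in the arrays with low hybridization controls alone, where P6 replicate 2 stood against the E18 arrays and the spread came from the E18 arrays only.

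**Figure D3:**
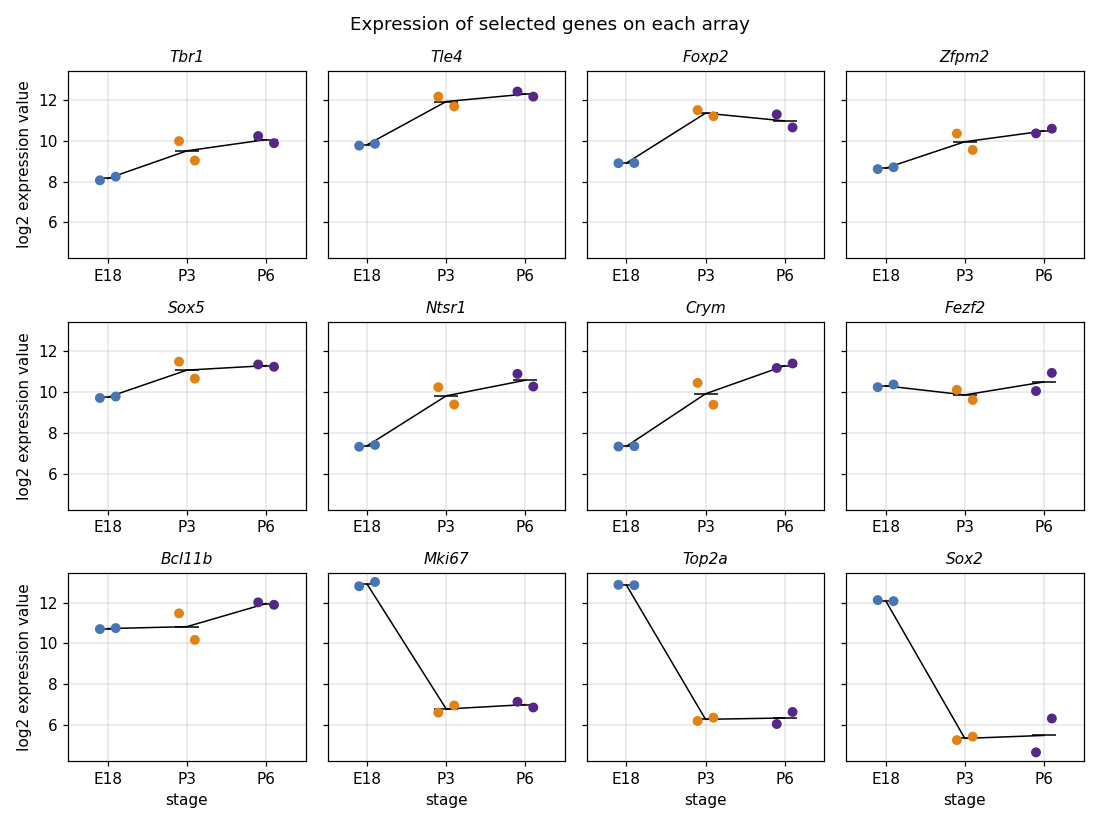
Log2 expression value of 12 genes on each array, 2 points per stage at E18, P3 and P6, with a line through the stage means. Crym goes from 7.34 at E18 to 11.29 at P6, and Top2a from 12.86 to 6.34.

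Aldoc, Pbk and Apoe were the genes named by the rule whose change was most positive in the second interval relative to the first, and B3galt1, Cyria and Stxbp5l the most negative. No gene list was tested for this difference. Limma called 3000 genes whose change from P3 to P6 differed from their change from E18 to P3, and 5282 genes that differed among the 3 stages. Of the 3000, 2280 were more positive and 720 more negative in the second interval. Of these, 2141 of the positive genes were already called lower at P3 and 710 of the negative genes higher, so the difference mostly restates the first interval. Both intervals share the P3 arrays, so noise in those arrays enters with a weight of 2. The largest positive differences were in the glial genes Aldoc (8.08 ± 0.74 log2 units, SE, adjusted p = 0.000917), Apoe (7.27 ± 0.88, adjusted p = 0.00257) and Gja1 (6.94 ± 1.19, adjusted p = 0.00966), and in Pbk (7.29 ± 0.38), Cdca5 (7.06 ± 0.46) and Celsr1 (6.96 ± 0.34). Celsr1 already stood at 4.11 log2 units at P3 and had little room to fall again. The largest negative differences were in B3galt1 (-4.91 ± 0.73), Cyria (-4.73 ± 0.60), Stxbp5l (-4.67 ± 0.55), the phosphatase gene Dusp6 (-4.57 ± 0.38), Gabrb2 (-4.40 ± 0.42) and Mdga2 (-4.28 ± 0.51), with adjusted p at most 0.00583. Gja1 lost its call without P3 replicate 2 (7.11, adjusted p = 0.0723). With the hybridization control level as a covariate, 7 of these 12 genes lost their calls: Aldoc (6.50, adjusted p = 0.0615), Apoe (4.73, 0.0517), Gja1 (3.22, 0.0733), B3galt1 (-3.59, 0.166), Cyria (-3.18, 0.072), Stxbp5l (-5.12, 0.079) and Gabrb2 (-3.85, 0.0528).

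With quantile normalization 52.6% of these differences were positive, against 76%, and the median of all genes moved from 0.35 to -0.09. The count was 6429 without P3 replicate 1, 1930 without P3 replicate 2, 1692 without P6 replicate 2, 1324 and 1253 without E18 replicate 1 or 2, and 226 with the hybridization control level as a covariate. For the 3 stages together it was 8665 without P3 replicate 1, and 2472 and 2383 without E18 replicate 1 or 2.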

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

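Leaving out each array and the test of unequal change were planned, and the other tests in this part were chosen after the results were seen. The change in 3000 genes differed between the intervals E18 to P3 and P3 to P6, by limma's test of the difference itself. The count was 226 with the hybridization control level as a covariate.

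The first pattern is the high level of proliferation and progenitor genes at E18, in a sort meant to hold postmitotic neurons. Microglia markers cannot decide whether projection neurons were a lower share at E18, because other cell types need not enter a sort equally. The tested microglia markers had a median of -0.99 log2 units from E18 to P6 (interquartile range -1.77 to -0.40), against -4.95 (-5.88 to -3.14) for the proliferation genes. The microglia median was -0.28 without P6 replicate 1, -1.66 without P6 replicate 2, and -1.95 from E18 to P3. These values speak only against an equal rise of all other cell types at E18. With the hybridization control level in the fit, the proliferation median was -4.886. That fit sets P6 replicate 2, the only later array with low hybridization controls, against the E18 arrays. With 1 such array, the lower controls of the E18 arrays cannot be excluded as a cause. RNA of progenitor cells in the E18 sort was not measured apart, because no array here holds progenitors alone. The fall of 12 of 14 tested radial glia and progenitor markers is part of the pattern itself. A change within the labelled neurons alone would require high cell-cycle genes in postmitotic cells. With 22 of 23 proliferation genes called lower at P6, at a median of -4.95, the values argue against it. The stage itself, with progenitors more numerous in cortex before birth, stays open and untested, because the E18 arrays are the only ones of their age. Labelling also differed, with 1 day from injection to collection at E18 and 2 days at P3 and P6. This cannot be told apart from the stage.

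The second pattern is the higher level of glycolysis and presynaptic genes at P6 than at P3. Glial markers were also higher, with medians of 0.91 for the microglia list and 0.77 for the astrocyte list, the latter not called by camera. The excess of 3' over 5' signal of Actb was 1.19 and 1.76 at P3 and 1.06 and 0.82 at P6. For Gapdh the stages overlapped, with 2.55 and 1.68 at P3 and 2.08 and 1.79 at P6. A change in the share of cells or in RNA quality was not tested apart from the stage. An effect of the P3 array that stands apart, replicate 2, cannot be told apart from the stage, because without it 1 P3 array is left and the spread comes from the other stages. The medians were then 0.569 for glycolysis (camera adjusted p = 0.000239) and 0.325 for presynaptic genes (0.00114), against 0.725 and 0.428 with all arrays. The level of the hybridization controls cannot be told apart from the stage either, because with it in the fit the glycolysis median was 0.643 with the call lost (camera adjusted p = 0.0519), and only 1 P6 array shares the P3 level. A difference with age stays open and was not tested apart from these.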

How the results depend on the processing

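Averaging the E18 arrays, the control-level fits and the fits without high 18S arrays were chosen after seeing the data. Averaging the E18 arrays gave 2452, 0, 2366, 1258 and 2431 calls for P3 minus E18, P6 minus P3, P6 minus E18, the unequal change and the 3 stages, with fewer degrees of freedom and without the closely matched E18 pair in the spread, and each of the 2452 and 2366 genes was also called with all 6 arrays. The hybridization control level as a covariate rests on the difference between the P6 arrays. It gave 1279 genes for P3 minus E18, 226 for the unequal change, 2230 for the 3 stages and 0 lists for P6 minus P3. Arrays with low controls alone gave 10229 genes for P6 minus E18, and those with high controls alone 57 genes and 0 lists for P6 minus P3. The 18S level as a covariate, which pairs P3 replicate 2 with P6 replicate 1, gave 516 genes for P6 minus P3. Without the arrays of high 18S the counts were 10871, 6977, 10225, 9395 and 11863 genes and 5 lists for P6 minus P3, because only the E18 arrays then gave a spread. Testing each probe set gave 8945, 6923 and 8000 calls for P3 minus E18, P6 minus E18 and the 3 stages, since more features were tested. Array weights gave 1805 genes for the unequal change. Lists called for P6 minus P3 numbered 7 with no filter and 5 with quantile normalization. With an estimated correlation 0, 0 and 0 lists were called, with 4, 0 and 4 at an unadjusted p under 0.05, and fry called 19 for P3 minus E18 and 0 for P6 minus P3. The estimated form uses the 3 residual degrees of freedom, so its lost calls do not show correlation as their cause. The replicate numbers did not pair the arrays, as same-numbered deviations correlated at -0.169, 0.0487 and -0.2388 between stages. The replicate block gave 6 lists for P6 minus P3, 5201 genes for P3 minus E18 and 0 for P6 minus P3, ended no list call, and called C1qa and Bcl11b for P6 minus E18 (adjusted p = 0.0122 and 0.029). Leaving out each array in turn gave 2397 to 7871 genes for P3 minus E18, 0 to 3922 for P6 minus P3, 2338 to 6161 for P6 minus E18, 1253 to 6429 for the unequal change and 2383 to 8665 for the 3 stages, with 11 to 12, 3 to 9 and 11 to 12 lists. Over these fits Bcl11b lay between -0.558 and 0.74 for P3 minus E18, Fezf2 between -0.256 and 0.636 for P6 minus E18, and for P6 minus P3 Sox5 between -0.197 and 0.634 and Syt6 between -0.743 and 0.623. Signs also turned for P6 minus P3 in Sox5 (-0.093 with quantile normalization, -0.291 with the mean of probe sets) and Bcl11b (-0.018 with that mean), and without high 18S arrays in Tbr1 (-0.098), Sox5 (-0.254) and Syt6 (0.659). With the hybridization control level, P3 minus E18 was 0.442 for Fezf2 and -0.033 for Bcl11b. Where no cause is given, the cause was not tested. No called list changed direction in the alternatives in which lists were tested, and apart from those signs the named genes kept theirs.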

Other observations

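Several gene groups outside the lists described so far held called members that went opposite ways. Between E18 and P3 the callosal and upper layer list had 4 rises and 5 falls among 16 genes (4 and 7 adjusted over the list alone), and camera did not call it (adjusted p = 0.715). Lhx2, a factor of cortical progenitors as well as upper layers, fell 45.6-fold, and Rasgrf2 rose 3.48-fold. The subplate and layer 6b list had 5 rises and 3 falls among 11 (6 and 3 adjusted over the list alone; camera adjusted p = 0.366). The dopamine receptor gene Drd1 rose 10.3-fold, while Ccn2, a subplate marker, fell 12.1-fold and Lpar1 5.87-fold. Ccn2 lost its call with the hybridization control level as a covariate (-3.36, adjusted p = 0.0522). From E18 to P6 the subplate genes Gabra5 and Cplx3 rose 7.27-fold and 4.56-fold, and Ccn2 fell 4.62-fold. Axon guidance genes had 11 rises and 13 falls among 49 from E18 to P3 (14 and 13 adjusted over the list alone; camera adjusted p = 0.49), with the secreted guidance genes Ntn4 down 13.3-fold and Slit2 8.70-fold. From E18 to P6 the ephrin gene Efna3 rose 7.20-fold and Sema3e 6.19-fold. Among cadherins, Cdh9 rose 15.8-fold from E18 to P3, and the list had 6 rises and 3 falls among 25, also adjusted over the list alone (camera adjusted p = 0.0941).

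Glycolytic genes also split between E18 and P6, with 5 rises and 4 falls among 15 (5 and 5 adjusted over the list alone; camera adjusted p = 0.852). The neuronal enolase gene Eno2 and the phosphofructokinase gene Pfkp rose 12.9-fold and 6.05-fold, while the hexokinase gene Hk2 fell 4.59-fold and the glucose transporter gene Slc2a1 5.20-fold. Immediate early genes had 9 falls and 1 rise among 20 from E18 to P3, also adjusted over the list alone (camera adjusted p = 0.127), with Fos down 11.1-fold and Jun 7.67-fold. Imprinted growth genes had 4 rises and 5 falls among 13, also adjusted over the list alone (camera adjusted p = 1), with Mest down 20.3-fold. Apoptosis genes had 2 rises and 8 falls among 18, also adjusted over the list alone (camera adjusted p = 0.297), with Casp6 down 5.21-fold. Interneuron markers had 2 rises and 4 falls among 10 (3 and 5 adjusted over the list alone; camera adjusted p = 0.65), with Dlx1 down 7.36-fold. Vascular and meningeal markers had 4 falls among 13, also adjusted over the list alone (camera adjusted p = 0.467), with Rgs5 down 4.97-fold and Cldn5 3.46-fold, the latter not called with the hybridization control level as a covariate (-2.03, adjusted p = 0.0556). Oligodendrocyte lineage markers had 1 rise and 3 falls among 9, also adjusted over the list alone (camera adjusted p = 0.919). Oxidative phosphorylation genes had 2 rises and 5 falls among 60 (0 and 1 adjusted over the list alone; camera adjusted p = 0.467), and cholesterol synthesis genes 1 rise and 4 falls among 19 (1 and 3 adjusted over the list alone; camera adjusted p = 0.97). From E18 to P3 fry did call the callosal (adjusted p = 0.0074), imprinted (0.0096), vascular (0.01), immediate early (0.01), glycolysis (0.043), apoptosis (0.047) and interneuron (0.047) lists. It did not call the subplate, axon guidance, cadherin, oligodendrocyte, oxidative phosphorylation and cholesterol lists (adjusted p at least 0.062). Of the lists too small to test, the 3 Cajal-Retzius genes had a median of 0.00 and the 3 red blood cell genes 0.12 from E18 to P3, with 0 members called in limma's fit.

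From E18 to P6 the callosal and upper layer list had 2 rises and 6 falls among 16, also adjusted over the list alone (camera adjusted p = 0.442, fry adjusted p = 0.0068). Lhx2 fell 38.0-fold, Mest 19.2-fold, Ntn4 7.72-fold, Dlx1 7.53-fold, Slit2 7.06-fold, and the pericyte genes Rgs5 and Pdgfrb 4.31-fold and 4.15-fold. Cdh9 rose 19.6-fold, Klf9 7.11-fold and Lpl 5.73-fold, each called by limma.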
